A study of Mus musculus with 15 samples.

How the data were processed

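Male TT2 mouse embryonic stem cells (C57BL/6 x CBA) were profiled by native ChIP-seq for H3K9me3, H3K27me3, H3K4me3 and panH3 and by RNA sequencing after depletion of ribosomal RNA, with paired-end Illumina reads, per the labels. Per the submitters' processing notes, BWA and SAMtools were used and the genome was mm9. Versions, the counting tool, and filters for duplicates and mapping quality are not given in the sources used here. Groups (mark and cell number) and the replicate letters a, b and c were taken from the labels.

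The authors deposited RPKM values (read density scaled to depth and length), per the file headers, with 1 column per library and no pooling of libraries. The bin table covers 98085 bins of 2 kb in 11 libraries, which its authors describe as random. The bins make up 7.39% of consecutive positions, and 4470 were 0 in every library. The panH3 columns carry no unit in the header and were taken as RPKM, since they have the same mean and the same kind of steps as their neighbours. The start-site table holds H3K4me3 RPKM in 74866 windows of 1 kb for 25727 genes. The gene table holds H3K27me3 RPKM within 1 kb of the start site and RNA RPKM over exons, per the file headers, for 28373 transcripts of 22035 genes, beside other columns of exon and gene length in base pairs that the authors deposited and that were not analysed here. No bin exceeds 5 RPKM, and no H3K4me3 window exceeds 50 RPKM (100 at 10000 cells), so the strongest windows appear to be left out of these tables. Levels of the top windows, and shares of them recovered in another library, are those among the windows kept. The start-site table also holds 2 columns of another series, which were not used. Of 27600 RefSeq IDs, 26942 were found in the reference table of gene names; symbols were taken from the deposited tables. RNA was listed at 0 in 20.4% of transcripts.

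In windows of equal length RPKM values are whole multiples of what 1 read is worth, and over 99% of non-zero low values matched such a multiple to 2 decimals in every ChIP library. This gave each library's depth, from 13.03 to 47.3 M reads in the bin table and 16.6, 1.07 and 1.86 M for H3K4me3 at 100000, 10000 and 5000 cells. A typical 2 kb bin therefore rests on 9 to 40 reads, and a start-site window at 10000 or 5000 cells on 2. Depth of the RNA library was not recovered.

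The values are not counts, so tests were run on log2(RPKM + 0.1). H3K9me3 (a, b, c) was compared with panH3 (a, b) at 1000 cells, and H3K9me3 was fitted against log10 of the cell number over its 6 libraries, with limma 3.58.1 in R 4.3.3 (robust moderation with an intensity trend, two-sided, Benjamini-Hochberg threshold 0.05) in bins above 0 in at least 1 of the libraries compared. Values were not scaled further. On simulated bins with the real means and depths and a dispersion of 0.02, with 200 bins changed, the first test recovered 10% of changes of 1 log2 unit and 76% of changes of 2 log2 units with 1 false call among 93516 bins. The slope test recovered 0% and 51% with 0 false calls among 93524 bins. The letters a and b are shared by H3K9me3 and panH3, but the a minus b deviations of the 2 marks correlated at -0.00954, and no label pairs them, so the libraries were not paired.

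All other comparisons rest on 1 library per group and carry no p-value. Spearman correlations were taken across windows above 0 in at least 1 library of the mark, and across genes between H3K27me3 and RNA. Recovery is the share of the top 5% of windows of the library with the most cells that is also in the top 5% of another, with an exact Clopper-Pearson 95% interval. Each of 11 gene lists, fixed before the data were examined together with the tests and the first set of alternatives, is given as the median of its members with its percentile among 10000 random lists of equal size; for differences between cell numbers the random lists were matched on mean level in 20 classes. Where several rows carry 1 symbol, the row with the highest mean over the mark's libraries stands for the gene. Bins were assigned to genes and start sites by overlap with the gene table (within 1 kb for start sites), and the chromosomes by the mean of bins above 0. Contrast is the mean of the top 5% of windows over the mean of windows below the median, both ranked in the other libraries of the mark. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

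Named genes followed a rule fixed at the same time. From each list it takes up to 4 members with the highest level in the library of most cells, or of RNA, and the member with the lowest. To these it adds, per gene table, the 8 genes with the highest level and the 4 largest rises and falls between the most and the fewest cells among genes with a mean of at least 1 RPKM, the 8 genes with the highest RNA, and the 5 most extreme bins per bin result. Not every gene that the rule names is reported here. Gene families, genes summarised over 5 or more bins and genes with both H3K27me3 and RNA were chosen after their values were seen. Alternatives tried were pseudocounts of 1 and 0.01, a minimum mean of 0.2 RPKM, centring, all 6 H3K9me3 libraries, leaving out each library, a replicate block, other top shares (1% and 10%), subtraction of or division by panH3, other RNA thresholds (0.5 and 5 RPKM) and, added later, voom on the recovered reads, thinning to the total of the shallowest library, all transcripts and leaving out chromosomes. Thinning made library totals equal and not the reads inside the windows, which for H3K4me3 were 7.24%, 31.4% and 15.5% of the totals.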

Results

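The series profiled histone marks and RNA in male TT2 cells, a mouse embryonic stem cell line from a C57BL/6 x CBA cross, over a range of cell numbers. Chromatin was immunoprecipitated without crosslinking (native ChIP-seq) with antibodies against H3K9me3, a mark of heterochromatin, H3K27me3, the mark laid down by Polycomb repressive complexes, and H3K4me3, a mark of active promoters. An antibody against histone H3 whatever its modification (panH3) followed nucleosome density. The 15 libraries comprised 6 of H3K9me3, 3 of H3K27me3, 3 of H3K4me3, 2 of panH3 and 1 of ribosomal RNA-depleted total RNA from 1000 cells. H3K9me3 was measured once each in 1000000, 100000 and 10000 cells and in 3 libraries of 1000 cells (a, b and c). H3K27me3 was measured once each in 100000, 10000 and 1000 cells. H3K4me3 was measured once each in 100000, 10000 and 5000 cells, and panH3 in 2 libraries of 1000 cells. The labels do not say whether libraries of equal cell number came from separate cultures, so p-values measure only the spread between these libraries. All groups other than H3K9me3 and panH3 at 1000 cells have no replicate check.

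The depth behind the values, recovered from the smallest steps of the deposited RPKM, was 45.5 M reads (M for 1000000) for H3K9me3 in 1000000 cells, 20.3 M in 100000 cells and 13.4 M in 10000 cells. The libraries of 1000 cells held 17.6, 34.9 and 27.2 M reads for H3K9me3 a, b and c and 47.3 and 42.2 M for panH3 a and b. H3K27me3 held 19.7, 15.3 and 13.03 M reads at 100000, 10000 and 1000 cells. H3K4me3 held 16.6 M reads at 100000 cells, but 1.07 M at 10000 cells and 1.86 M at 5000 cells, so that 1 read in a 1 kb window was worth 0.938 and 0.539 RPKM in these shallow libraries. H3K9me3, H3K27me3 and panH3 were given in 98085 bins of 2 kb spread over the genome (mm9), H3K4me3 in 74866 windows of 1 kb around transcription start sites, and H3K27me3 and RNA together for 28373 transcripts of 22035 genes.

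Comparison of H3K9me3 with panH3 at 1000 cells asked where the mark stood above or below nucleosome density. H3K9me3 was lowest over expressed genes. In bins within 1 kb of the start site of a gene with RNA of at least 1 RPKM it averaged 0.160 ± 0.006 RPKM (SD, n = 3) against 0.451 ± 0.002 for panH3 (SD, n = 2), and 1323 of 1595 such bins were lower than panH3 while 36 were higher. Bins touching 19 genes with symbols of Rpl or Rps and a number were lower in 46 of 49 cases and higher in 0. They stood at 0.124 ± 0.008 RPKM against 0.459 ± 0.005. Such symbols belong to ribosomal protein genes, which encode the protein part of the ribosome, but also to S6 kinase genes. The kinds of gene were not separated. Start sites of genes with RNA under 1 RPKM were lower in 433 and higher in 120 of 1485 bins. Bins that touch no gene went the other way, with 11654 higher and 6856 lower of 57808 and a mean of 0.484 ± 0.003 RPKM against 0.413, whereas bins touching a gene were lower in 16302 and higher in 2570 of 35767.

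Across all bins, limma with Benjamini-Hochberg adjustment called 14224 of 93575 higher (15.2%) and 23158 lower (24.7%) in H3K9me3, with a median log2 difference of -0.10. Centring each library on its median moved the split to 20312 higher and 18564 lower, with a median log2 difference of 0.08, so the balance of higher against lower bins depends on the scaling. The directions given for start sites, Rpl and Rps genes and bins with or without a gene were the same under both scalings. Fold changes are on the scale of log2(RPKM + 0.1), which understates the change of bins with low values.

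Among the gene lists fixed beforehand, germline genes had the most bins below panH3, with 27 lower and 3 higher of 46, and the same 27 and 3 when adjusted over the list alone (22 and 4 with centring). Tex14, which forms the intercellular bridges of germ cells, was lower in 6 of 6 bins (0.187 ± 0.024 against 0.75 ± 0.017 RPKM), and Tex11, a meiotic gene of the X chromosome, in 7 of 12. Tdrd9, a germline RNA helicase, was lower in 3 and higher in 1 of 7 bins. Y-linked genes were higher in 6 and lower in 0 of 19 bins, with the same counts adjusted over the list alone and with centring, including 2 of 5 bins in Uty, 2 of 6 in Zfy2 and 1 of 6 in Usp9y. Fibroblast markers were lower in 10 and higher in 1 of 25 bins (11 and 1 adjusted over the list alone), which became 5 and 1 with centring. Tissue-specific genes were lower in 5 and higher in 1 of 16 (7 and 2 adjusted over the list alone), which became 3 and 2 with centring. Imprinted genes were lower in 7 and higher in 5 of 25 bins, the same counts as when adjusted over the list alone, and moved to 5 and 5 with centring. Lineage regulators were lower in 7 and higher in 3 of 41 bins (5 and 3 adjusted over the list alone), a direction that turned to 4 lower and 7 higher when the libraries were centred. Of all bins touching a gene, 45.6% were lower and 7.19% higher. Germline bins were lower in 58.7%, fibroblast markers in 40%, tissue-specific genes in 31.25%, imprinted genes in 28% and lineage regulators in 17.1%. Among these lists only germline genes were thus lower more often than bins touching a gene. Y-linked bins were higher in 31.6%. The other lists had under 10 tested bins and were not counted.

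Gene families were also counted, chosen after the values were seen and without a test against other bins. Vomeronasal receptor genes, a large family of pheromone receptors, were higher in 36 and lower in 1 of 162 bins, at 0.497 ± 0.028 RPKM against 0.387 ± 0.011. Cytochrome P450 genes were higher in 21 and lower in 11 of 96 bins, protocadherin genes higher in 24 and lower in 12 of 172, olfactory receptor genes higher in 14 and lower in 8 of 132, and keratin genes higher in 8 and lower in 3 of 31. Zfp zinc finger genes were lower in 222 and higher in 38 of 393 bins, and collagen genes lower in 45 and higher in 13 of 185. In olfactory receptor and protocadherin genes 10.6% and 13.95% of bins were higher, against 7.19% of bins touching a gene and 15.2% of all bins. In collagen genes 24.3% of bins were lower, against 45.6% of bins touching a gene and 24.7% of all bins. Serpin genes had 8 lower and 5 higher of 38 bins, which became 8 and 8 with centring, while the other families kept their direction.

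**Figure D1:**
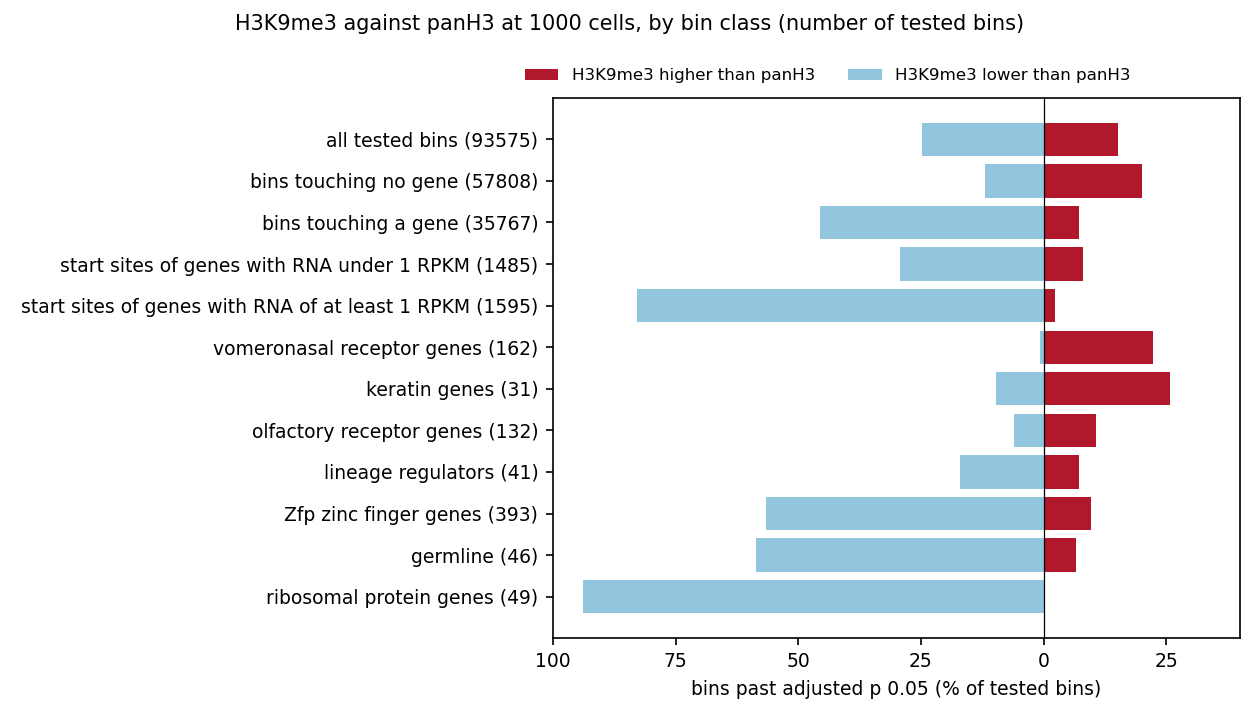
Share of tested 2 kb bins (x axis, percent) in which H3K9me3 at 1000 cells (3 libraries) was higher (red, right) or lower (blue, left) than panH3 (2 libraries) at an adjusted p of 0.05 with limma, for bin classes on the y axis with their number of tested bins. The class labelled ribosomal protein genes had 46 of 49 bins lower and vomeronasal receptor genes 36 of 162 bins higher. That class holds genes with symbols of Rpl or Rps and a number, which can include S6 kinase genes. Lineage regulators, 7 lower and 3 higher as drawn, turned to 4 lower and 7 higher when libraries were centred on their medians.

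Of 2004 genes with at least 5 tested bins, 773 had most of their bins lower and 31 had most of them higher. Every tested bin was lower in the 8 genes with the lowest median change, which were chosen after the values were seen. Setd2, the H3K36 methyltransferase that acts on transcribed genes, stood at 0.0805 ± 0.0097 RPKM against 0.759 ± 0.017 over 7 bins (median log2 -2.38, RNA 26.3 RPKM). Ankrd11, a chromatin regulator, had a median log2 difference of -2.37, Pafah1b1, a regulator of dynein, -2.36, Tpr, a protein of the nuclear pore basket, -2.31, and Trim37, a ubiquitin ligase, -2.27. Gigyf2, a translational repressor, Helz, an RNA helicase, and Usp34, a deubiquitinase, followed at -2.23, -2.18 and -2.17. Of these 8 genes, all but Setd2 lie on chromosomes 1, 8 and 11, where every bin library was also higher than on other autosomes. At the other end, Cep57l1, a centrosomal protein gene, had 4 bins higher and 3 lower of 7, at 1.04 ± 0.086 RPKM against 0.476. Galk2, a sugar kinase gene, had a median log2 difference of 1.02, the major urinary protein gene Mup2 0.95, the peptidase gene Naalad2 0.90, and the guanylate cyclase gene Gucy1a2 0.84, with 7 of 11 bins higher. The overlapping protocadherin genes Pcdhga7, Pcdhga8 and Pcdhgb4 shared the same 7 bins, of which 5 were higher and 1 lower (0.770 ± 0.104 against 0.460 ± 0.010 RPKM).

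The single bins with the largest difference above panH3 lay on chromosome 16 at 61326001 to 61328000, away from annotated genes (log2 2.55 ± 0.27 SE), on chromosome X at 9186001 to 9188000 within 100 kb of Dynlt3 (2.44 ± 0.21), and on chromosome 7 at 50142001 to 50144000 near the vomeronasal receptor genes Vmn2r62 and Vmn2r63 (2.38 ± 0.23). Others lay on chromosome 12 at 3020001 to 3022000 (2.37 ± 0.17), and on chromosome 2 at 174980001 to 174982000 in 0610010B08Rik (2.36 ± 0.18). Those furthest below panH3 touched Zfp142 on chromosome 1 at 74624001 to 74626000 (log2 -2.94 ± 0.25 SE), Rbbp5, a subunit of H3K4 methyltransferase complexes (-2.92 ± 0.27), Armc9 (-2.83 ± 0.27), Rbm34 (-2.80 ± 0.26) and the divergent genes Trp53 and Wrap53 (-2.75 ± 0.26), all on chromosomes 1, 8 and 11, where panH3 was higher and the log2 scale can reach lower values. The limma adjusted p of these 10 bins ranged from 4.33e-10 to 3.11e-07. The highest H3K9me3 signal over the 6 libraries, 3.91 ± 0.47 RPKM (SD, n = 6), was on chromosome 13 at 66382001 to 66384000, where panH3 was 1.13 ± 0.10. The bin on chromosome 4 at 146034001 to 146036000 in Gm13034, next to the zinc finger gene Zfp600, followed at 3.77 ± 0.60. Next were those on chromosome 1 at 87776001 (3.63 ± 0.67, near Cab39), chromosome 6 at 124560001 (3.53 ± 0.55, near the complement genes C1ra and C1s) and chromosome 9 at 123842001 (3.5 ± 0.97, near the chemokine receptor genes Ccr1 and Ccr3).

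Across cell numbers, the question was whether the H3K9me3 profile of fewer cells matched that of 1000000 cells. At start sites of expressed genes H3K9me3 averaged 0.271 RPKM in 1000000 cells, 0.258 in 100000, 0.168 in 10000 and 0.160 ± 0.006 in 1000 cells (n = 3). Over Rpl and Rps genes it averaged 0.234, 0.178, 0.117 and 0.124 ± 0.008. Over vomeronasal receptor genes it averaged 0.425, 0.488, 0.542 and 0.497 ± 0.028 RPKM. A slope on log10 of the cell number, tested in 93569 bins with limma, was significant in 1, on chromosome 8 at 83164001 to 83166000 in Frem3, an extracellular matrix gene. There H3K9me3 was 0.18 RPKM in 1000000 cells, 0.17 in 100000, 0.63 in 10000 and 0.71, 1.42 and 1.44 in 1000 cells, a slope of -0.81 ± 0.11 (SE) log2 per unit of log10 (limma adjusted p = 0.000634). Limma called 0 bins rising with cell number, where 5173 bins rose and 1875 fell at an unadjusted p under 0.05. Limma with voom weights on the recovered reads called 1771 rising and 102 falling, a pseudocount of 1 gave 99 rising, and leaving out the 10000-cell library gave 10. On simulated bins the slope test recovered 0% of changes of 1 log2 unit and 51% of changes of 2 log2 units, so the low count does not show that the profiles were alike.

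The Spearman correlation with the 1000000-cell library across bins was 0.775 for 100000 cells, 0.729 for 10000 cells and 0.797 ± 0.042 for the 3 libraries of 1000 cells, while pairs of 1000-cell libraries correlated with each other at 0.831, 0.813 and 0.888. Libraries a, b and c stood at 0.748, 0.821 and 0.822, with 17.6, 34.9 and 27.2 M reads. The 100000-cell and 10000-cell libraries held 20.3 and 13.4 M, so the order by cell number is confounded with depth. Thinned to equal library totals, the correlations were 0.657 at 100000 cells, 0.645 at 10000 cells and 0.647, 0.677 and 0.688 for a, b and c. With H3K27me3 at 100000, 10000 and 1000 cells the 1000000-cell library correlated at 0.404, 0.415 and 0.508. Bins are not independent replicates, so no p-value is given. Of the top 5% of bins at 1000000 cells, 70.3% (exact binomial 95% interval 69.0 to 71.6) were also in the top 5% at 100000 cells, 68.6% (67.2 to 69.9) at 10000 cells and 73.3% ± 3.45 (SD, n = 3) at 1000 cells, where unrelated lists would share about 5%. Library a recovered 69.3%, c 74.9% and b 75.6%, in the order of their depth. Between 1000-cell libraries the shared part ranged from 69.1% to 77.9%. These intervals, and those given for other shares, cover counting error only.

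H3K27me3 at start sites was concentrated on developmental regulators at every cell number. HOX genes, the homeobox clusters that pattern the body axis, had a median of 2.86 RPKM at 100000 cells, 3.29 at 10000 and 1.61 at 1000, against 0.28, 0.28 and 0.31 for all genes. Lineage regulators had medians of 2.11, 2.34 and 1.23 RPKM. Both lists lay at percentile 100 of 10000 random gene lists of equal size in each library. The highest genes at 100000 cells were Sox17, an endoderm factor (5.40, 5.02 and 3.23 RPKM at 100000, 10000 and 1000 cells), Otx1, a forebrain factor (5.24, 5.30 and 2.96), and Sfi1, a centrosomal protein gene (4.94, 5.89 and 7.75). They were followed by Lhx1 (4.64, 5 and 2.97), Hes7, an oscillator of somite formation (4.52, 4.79 and 2.89), Hoxb3 (4.45, 5.09 and 2.44), Pou4f2 (4.36, 4.14 and 2.63) and Tcfap2b (4.32, 5.19 and 2.79). Within the lists, Hoxb8 had 4.23, 5.52 and 2.5 RPKM, Hoxb5 3.92, 4.04 and 2.53, Hoxb6 3.92, 4.63 and 2.15, Nkx2-1, a lung and thyroid factor, 3.71, 4.67 and 2.24, and Irx3 3.63, 4.28 and 1.94. Of these, Hoxb8, Hoxb5 and Hoxb6 also lie on chromosome 11 and Irx3 on chromosome 8, while Nkx2-1 lies on chromosome 12. Hoxc5 and the B cell factor Pax5 were lowest of their lists at 100000 cells with 0.78 and 0.26 RPKM.

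Other groups carried less H3K27me3. Imprinted genes had medians of 0.70, 0.84 and 0.54 RPKM at 100000, 10000 and 1000 cells, led by the growth inhibitor Cdkn1c (3.56, 3.36 and 2.21), Gnas (2.81, 2.97 and 1.76), Kcnq1ot1 (2.77, 1.90 and 1.55) and Dlk1 (2.05, 2.17 and 0.63). Tissue-specific genes had medians of 0.55, 0.62 and 0.54, with Ins2, Lor and Mpo at 1.36, 1.33 and 1.28 RPKM in 100000 cells. Germline genes had medians of 0.52, 0.60 and 0.45, led by Tdrd1 (1.81, 2.29 and 0.92) and Slc25a31 (1.79, 1.73 and 0.93). Fibroblast markers, included for feeder cells, had 0.415, 0.40 and 0.43, led by the growth factor receptor Pdgfra (2.33, 2.61 and 1.32). Pluripotency genes had 0.29, 0.30 and 0.335, near all genes, although Esrrb reached 3.68, 4.08 and 1.72 RPKM and Lefty1 1.45, 1.5 and 1.52. Housekeeping genes had 0.09, 0.08 and 0.16, histone genes 0.07, 0.04 and 0.11, Y-linked genes 0.08, 0.105 and 0.10, and genes of the 2-cell-like state 0.205, 0.215 and 0.15.

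**Figure D2:**
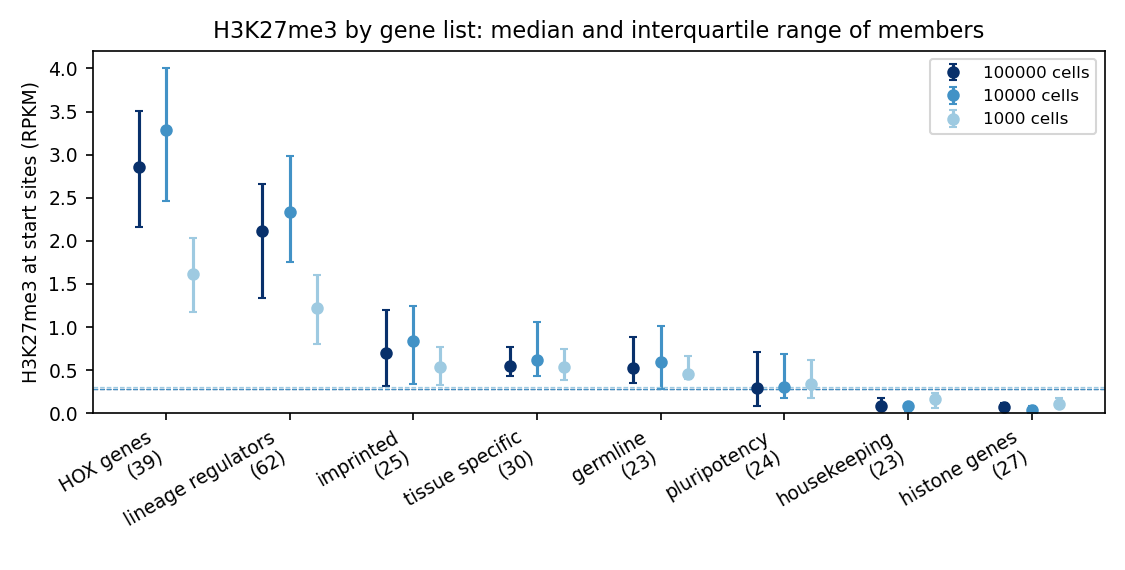
H3K27me3 at start sites (y axis, RPKM) for 8 gene lists (x axis, number of members below each), as the median (points) and interquartile range (bars) of members in the libraries of 100000, 10000 and 1000 cells; dashed lines give the median of all genes. HOX genes had medians of 2.86, 3.29 and 1.61 RPKM and housekeeping genes 0.09, 0.08 and 0.16.

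The 1000-cell library had lower values at marked genes. All 39 HOX genes and 57 of 62 lineage regulators were lower at 1000 than at 100000 cells, by a median log2 of -0.79 and -0.68, and so were 1708 of 1856 genes with a mean of at least 1 RPKM (92.03%, median log2 -0.60). Among random lists matched on level the differences of HOX genes and lineage regulators stood at percentiles 1.48 and 5.84, which became 0.32 and 1.93 with a pseudocount of 1 and 5.55 and 3.71 with the mean over the rows of a gene. The largest differences among these were at Agbl3 (log2 -2.20), the signalling ligand gene Wnt3 (-2.20), the cannabinoid receptor gene Cnr1 (-2.17) and Camk2n1 (-2.05). The largest in the other direction were at A730008H23Rik (1.43), the immune receptor gene Pdcd1 (1.16), the metallothionein gene Mt1 (0.94) and the noncoding RNA gene Tug1 (0.87). All of the latter lie on chromosomes 1, 8 and 11, where every bin library was higher than on other autosomes. Of the genes with the largest falls only Wnt3 does. Whether the level of these chromosomes bears on the rises was not tested. Of 24 pluripotency genes, 17 were higher and 7 lower at 1000 cells, with a median log2 of 0.34 (percentile 99.7 among random lists matched on level). With 1 library per cell number these differences have no replicate check.

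Across 93011 bins, H3K27me3 correlated with the 100000-cell library at a Spearman coefficient of 0.819 for 10000 cells and 0.705 for 1000 cells, and across 27508 transcripts of the gene table at 0.871 and 0.777. Of the top 5% of bins at 100000 cells, 69.5% (exact binomial 95% interval 68.2 to 70.9) were in the top 5% at 10000 cells and 55.4% (53.9 to 56.8) at 1000 cells. The bins with the highest mean H3K27me3 lay on chromosome X at 123302001 (4.58, 4.31 and 3.57 RPKM at 100000, 10000 and 1000 cells, with panH3 at 3.26) and on chromosome 8 at 47306001 near Helt (4.65, 4.57 and 3.15). Others lay in the Hoxc cluster on chromosome 15 at 102782001 (4.98, 4.93 and 2.42), in B4galnt2 on chromosome 11 at 95776001 (4.75, 4.64 and 2.80) and near Gsx2 and Pdgfra on chromosome 5 at 75468001 (4.40, 4.71 and 2.99).

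**Figure D3:**
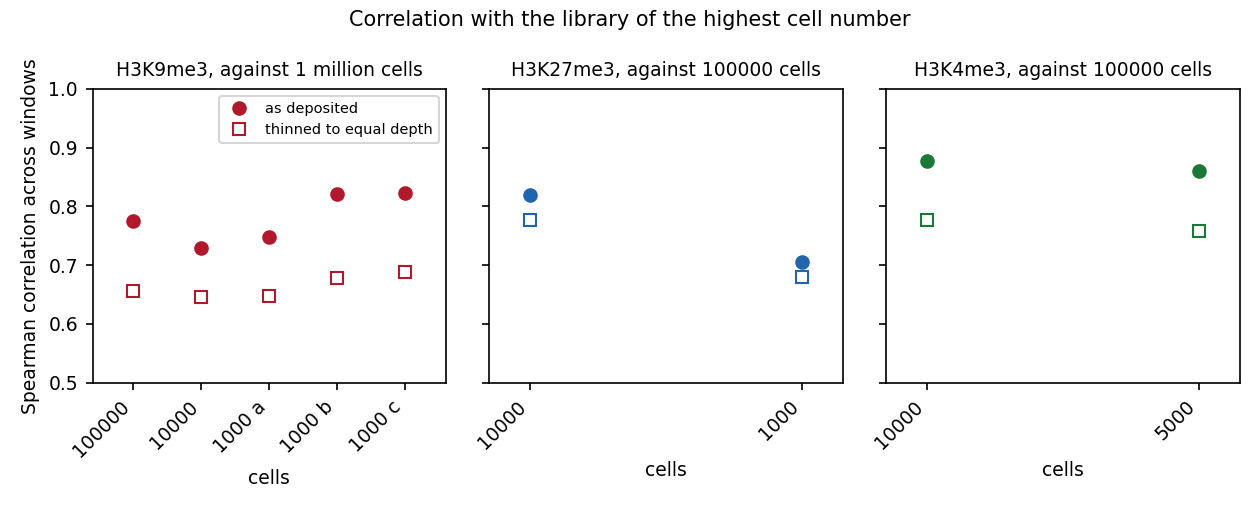
Spearman correlation across windows (y axis, no unit) of each library with the library of the highest cell number of its mark (x axis, cells), as deposited (filled) and with recovered reads thinned to the shallowest library of the mark (open). The axis starts at 0.5; as deposited, H3K9me3 lies between 0.729 and 0.822, H3K27me3 at 0.819 and 0.705, and H3K4me3 at 0.878 and 0.860.

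Comparison of H3K27me3 with RNA from the same number of cells asked how the mark related to transcript level. RNA was high for pluripotency and housekeeping genes, with medians of 29.1 and 35.5 RPKM against 1.02 for all genes. Zfp42, a marker of naive pluripotency, had 221.8 RPKM, Sall4 97.3, Dppa5a 95.1 and Pou5f1, the central pluripotency factor, 81.4, all with H3K27me3 of at most 0.18 RPKM at 1000 cells. Eef1a1, Hsp90ab1, Actb and Tubb5 had 748.9, 489.1, 453.7 and 281.5 RPKM of RNA. Histone genes, whose transcripts lack poly(A) tails, had the highest median of the lists, 60.3 RPKM, with 519.5 for Hist1h4d. HOX genes had a median of 0 RPKM, 22 of 39 being listed at 0 and none reaching 1, and lineage regulators 0.09, with Olig1 (3.42) and Olig2 (2.57) highest. Medians were 0.025 RPKM for tissue-specific genes, 0.115 for fibroblast markers, 0.035 for 2-cell-like genes, 0.07 for Y-linked genes, 2.49 for germline genes and 3.17 for imprinted genes. The highest members of these lists were Krt10 (1.57), Fn1 (38.5) and Sparc (33.7), Eif1a (46.4), Uty (3.65), Tex14 (39.9) and Airn (52.9) in that order. Eif1a stood apart from the 2-cell-like list, where the next member, Zscan4d, had 0.30 RPKM. The highest values of all belonged to Cdk8 (13336 RPKM), Zc3h7a (7635), Gphn (3039), the ribonuclease P RNA gene Rpph1 (2963), D130009I18Rik (2409), the RNase MRP RNA gene Rmrp (2372), Lars2 (2119) and Camk1d (1448), where reads from repeats or small RNAs inside a gene cannot be told from those of the gene itself.

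Across 22035 genes, H3K27me3 and RNA at 1000 cells had a Spearman correlation of -0.393 (-0.445 and -0.452 with H3K27me3 at 10000 and 100000 cells), over genes, which are not independent replicates. Median H3K27me3 was 0.43 RPKM in 11074 genes with RNA under 1 RPKM and 0.23 in 10961 others. Over the RNA quartiles of the latter it was 0.29, 0.24, 0.21 and 0.20. Of the 1124 genes in the top 5% for H3K27me3, 935 had RNA under 1 RPKM, or 83.2% (exact binomial 95% interval 80.9 to 85.3) against 50.3% of all genes. Among the genes in the top 5% for H3K27me3 at 100000 cells were some with RNA of at least 5 RPKM, chosen after their values were seen. Esrrb, a pluripotency factor with several start sites, had 73.8 RPKM of RNA and H3K27me3 of 1.72 RPKM at 1000 cells, Gbx2 9.51 and 2.66, the centromere gene Hjurp 11.4 and 2.72, Gnas 23.7 and 1.76, Crabp1 8.28 and 1.37, and 2610005L07Rik 44.9 and 4.33. In the same order, H3K27me3 at 100000 cells was 3.68, 3.16, 2.35, 2.81, 2.35 and 2.95 RPKM. Hjurp and 2610005L07Rik were thus higher at 1000 cells, and the others were lower.

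**Figure D4:**
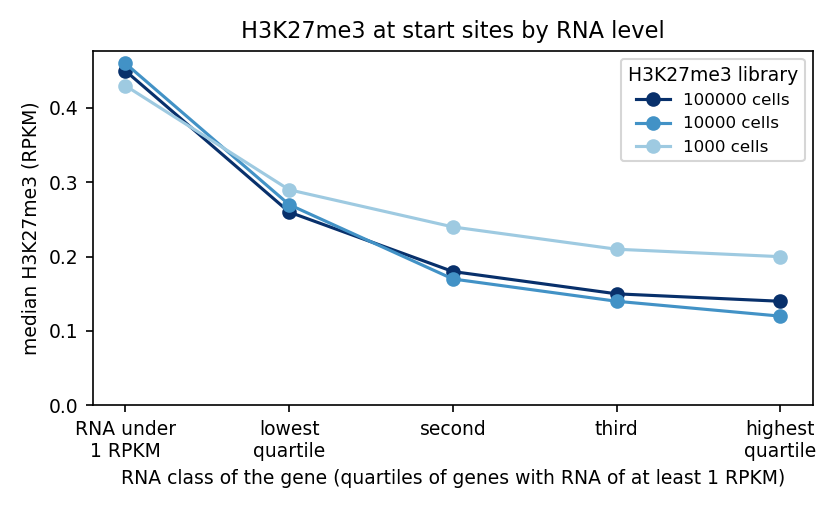
Median H3K27me3 at start sites (y axis, RPKM) of genes with RNA under 1 RPKM and of the quartiles of genes with RNA of at least 1 RPKM (x axis), for the H3K27me3 libraries of 100000, 10000 and 1000 cells. At 1000 cells the median was 0.43 RPKM in the genes with RNA under 1 RPKM and 0.20 in the highest quartile.

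H3K4me3 was strongest at start sites of housekeeping and pluripotency genes. Housekeeping genes had medians of 6.44 RPKM at 100000 cells, 60 at 10000 and 26.7 at 5000, against 1.39, 3.75 and 2.15 for all genes (percentile 100 in each). Pluripotency genes had 3.92, 26.3 and 12.4 RPKM (percentiles 98.9, 99.9 and 99.9). Gapdh had 11.7, 92.8 and 45.2 RPKM, Atp5b 10.8, 96.6 and 40.4, and Ppia 11.8, 83.4 and 35.6. Klf5 had 14.03, 78.8 and 33.4, Klf2 12.9, 68.4 and 47.4, and Esrrb 8.67, 78.8 and 35.6. Imprinted genes had medians of 2.5, 12.2 and 4.85, with Mkrn3 at 5.42, 68.4 and 19.4. Lineage regulators had 1.93, 3.75 and 2.15, with Eomes at 4.64, 21.6 and 11.3 and Irx3 at 5.12, 15 and 7. HOX genes had 1.32, 1.88 and 1.08, led by Hoxd8 (3.31, 14.1 and 3.77) and Hoxd1 (3.19, 11.3 and 2.15). Histone genes had 0.96, 8.44 and 3.23, fibroblast markers 0.93, 1.88 and 2.15, with Fn1 at 6.50, 36.6 and 23.7. Germline genes had 0.90, 0.94 and 0.54, with Tex14 at 3.13, 26.3 and 8.08, and tissue-specific genes 0.54, 0 and 0.54. Y-linked genes had 0.18, 0 and 0, and genes of the 2-cell-like state 0.24, 0 and 0. Among the latter Eif1a had 10.4, 98.4 and 47.9, but the next at 100000 cells, Tdpoz4, had 0.78, 0 and 0. The value of Eif1a therefore does not speak for its list.

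The highest windows at 100000 cells belonged to Gm10222 (49.2 RPKM, with 25.3 and 12.4 at 10000 and 5000 cells), Gm11168 (44.0, 27.2 and 31.2), Gm16869 (30.4, 32.8 and 24.2) and Gm10721 (29.6, 6.56 and 4.85), of which the last 3 lie in the first megabases of chromosome 9. Unlike most genes, all of these were lower at 5000 than at 100000 cells. Repeats were not tested, so reads from repeats in these windows cannot be told from H3K4me3 at a start site. Gm11973, Med26, a Mediator subunit gene, Irf2bp2 and Wnk1 followed with 20.7, 20.5, 20.1 and 19.5 RPKM. Of these, Gm11973 lies on chromosome 11 and Med26 and Irf2bp2 on chromosome 8, where every bin library was higher than on other autosomes. Between 100000 and 5000 cells, 13286 of 15045 genes with a mean of at least 1 RPKM were higher at 5000 cells, by a median log2 of 1.13 over all of them. The largest differences in this direction were at Pcdh10 (log2 3.57), 1700064H15Rik (3.52), Maoa (3.51) and Gm6410 (3.44). Pcdh10 had 0.18, 0 and 3.23 RPKM at 100000, 10000 and 5000 cells, so its difference rests on a few reads of 1 library, whereas 1700064H15Rik had 1.51, 39.4 and 18.3, Maoa 0.24, 5.63 and 3.77, and Gm6410 1.99, 45 and 22.6. Cdc42ep1, Gal3st1, Synj2 and Rundc3a had 2.77, 2.71, 2.41 and 2.41 RPKM at 100000 cells, 5.63, 3.75, 4.69 and 2.81 at 10000 cells, and were listed at 0 at 5000 cells, where 1 read is worth 0.539 RPKM. The reads in 42255 windows that do not overlap made up 7.24% of the library at 100000 cells, 31.4% at 10000 and 15.5% at 5000. Spearman correlations with the 100000-cell library were 0.878 and 0.860 across 73704 windows. Of its top 5% of windows, 57.9% (exact binomial 95% interval 56.3 to 59.5) and 57.6% (56.0 to 59.2) were in the top 5% at 10000 and 5000 cells. With the top 1% these shares became 33.6% and 36.9%. Windows above 50 RPKM (100 at 10000 cells) appear to be left out. The shares therefore cover only the windows kept and may differ with all windows.

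As deposited, H3K9me3 and H3K27me3 shared more of their strongest bins than independent lists would. Independent lists take all bins as alike, whereas chromosomes differed in level in every bin library, which can place the same bins in both lists. The overlap was not counted without those chromosomes, so it does not show that the marks themselves coincide. At 100000 cells 634 bins were in the top 5% of both marks, where independent lists give 252 (a ratio of 2.52), at 10000 cells 473 against 258 (1.83), and at 1000 cells 808 ± 21 (SD, n = 3 H3K9me3 libraries) against 252 (3.21 ± 0.08). The bin in Gm13034 was an example, with 4.59 RPKM of H3K9me3 and 3.25 of H3K27me3 at 100000 cells. When each value was divided by panH3 the ratio was 1.23 at 100000 cells, 0.867 at 10000 cells and 1.69 at 1000 cells, so that at 10000 cells the direction turned. The same panH3 values divided both marks, so their noise is shared between the lists.

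Chromosomes 1, 8 and 11 had a higher mean level than the other autosomes in every bin library. Relative to the median of 15 other autosomes, chromosome 1 stood at 1.52 ± 0.06 (SD over 11 libraries), chromosome 8 at 1.49 ± 0.01 and chromosome 11 at 1.44 ± 0.13, with a lowest value in any library of 1.42, 1.47 and 1.30. Chromosome X, present once in male cells, stood at 0.536 ± 0.049, and chromosome 6 at 1.12 ± 0.01. Chromosome Y differed between libraries, from 0.241 in H3K27me3 at 10000 cells to 1.01 in H3K9me3 at 1000000 cells. In panH3, 10 Mb segments of chromosomes 1, 8 and 11 ranged from 1.34 to 1.67 (47 segments) and those of the 15 others from 0.488 to 1.18 (195 segments), while chromosome 6 ranged from 0.904 to 1.08 before 120 Mb and from 1.49 to 1.72 beyond it. Leaving out chromosomes 1, 8, 11, X and Y and the end of chromosome 6, the comparison of H3K9me3 with panH3 called 10489 bins higher and 17326 lower of 70596, an alternative added after the data were seen.

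**Figure D5:**
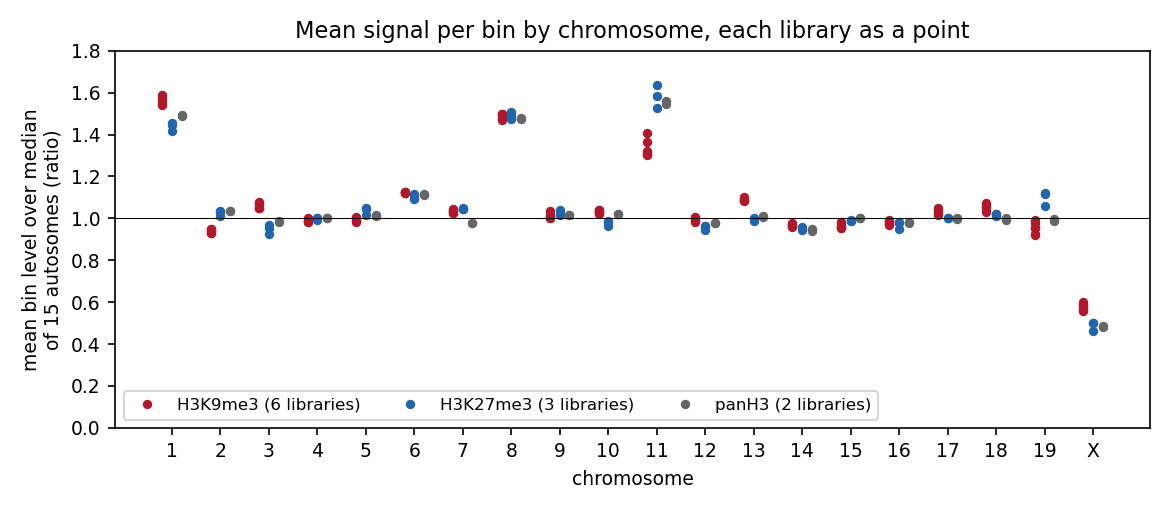
Mean bin level of each chromosome divided by the median of 15 autosomes (y axis, ratio) for chromosomes 1 to 19 and X (x axis), with a point for each of the 6 H3K9me3, 3 H3K27me3 and 2 panH3 libraries; chromosome Y is not drawn. Chromosomes 1, 8 and 11 lie at 1.30 or more in all 11 libraries and chromosome X between 0.464 and 0.5996.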

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

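The test of depth was laid down before its result was seen, and the other tests in this part were chosen only after the result was seen. The contrast between enriched and remaining bins was higher at 1000 than at 100000 cells for H3K9me3 and lower for H3K27me3. For H3K9me3 the contrast was 5.03 at 100000 cells and higher by 0.793, 0.760 and 0.706 in libraries a, b and c at 1000 cells. For H3K27me3 it was 5.51 at 100000 cells and differed by -2.06 at 1000 cells, where it was 3.44. At 10000 cells it was higher than at 100000 cells for both marks (5.97 and 5.89), and for H3K9me3 at 1000000 cells it was lower (4.17). The difference between the marks was not tested, since H3K27me3 has 1 library at each cell number.

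Depth of the H3K27me3 library at 1000 cells was not decided by thinning to the total of the shallowest library, which left the contrast at 100000 cells at 1.60 times that at 1000 cells but can hardly move a ratio of means (5.51 to 5.48 and 3.44 to 3.42). Unenriched chromatin alone, which would not pass panH3, remains open too. In 1476 bins strong for H3K9me3 the H3K27me3 library at 1000 cells (0.436 RPKM, with 0.263 at 100000 cells) stood at 1.18 times panH3 b. The interval of 1.13 to 1.23 covers spread over chromosomes only. These bins were picked for H3K9me3 at 10000 or more cells over 1.5 log2 above panH3 a, so panH3 a (0.327) is low by selection. That leaves panH3 b (0.370) as the comparison, with 1 library on each side. Reads from chromatin with H3K9me3 also remain open, since a fit of the 1000-cell profile as a mixture gave H3K9me3 a weight of 0.187 (0.191 and 0.184 on even and odd chromosomes), against 0.061 at 100000 and 0 at 10000 cells, beside 0.298 for panH3 and 0.501 for the 100000-cell H3K27me3 profile. Such reads may come from antibody binding to H3K9me3 or from mixing between libraries, which these values do not separate. A difference in the cells themselves was not tested.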

How the results depend on the processing

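Thinned, voom, all-transcript and chromosome alternatives were chosen only after the data were seen; the rest were laid down before. Of 371 alternative values for 134 results, 202 were counted as the same and 169 were not, of which 1 reversed. Counts of bins passed if within 1.5 times, and other values by direction or spread. For H3K27me3 and H3K4me3, with 1 library per cell number, that spread is not one between replicates, so small changes can fall outside it. Higher and lower bins were tallied separately. The turns under centring, in their balance and in the bins of lineage regulators, are therefore not the 1 reversal. For H3K9me3 against panH3, every setting kept both counts within 1.5 times, from 10489 to 20312 bins higher and 17326 to 25703 lower, and leaving out single libraries gave 9759 to 16475 higher and 15521 to 25897 lower. A replicate block on the letters gave 13555 higher and 22786 lower; the letters do not pair the libraries. Unless stated otherwise, the cause of a change was not tested. Depth limits H3K4me3 at 10000 and 5000 cells most, where a read is worth 0.938 and 0.539 RPKM.

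The number of bins whose H3K9me3 rose with cell number was 99 with a pseudocount of 1 and 1771 with voom, which also called 102 falling; leaving out single libraries gave 0 to 10 rising, the 10 without the 10000-cell library, and 1 falling each time. H3K9me3 correlations at 100000, 10000 and 1000 cells were 0.831, 0.796 and 0.849 as Pearson with a pseudocount of 1, 0.693, 0.632 and 0.729 in bins of at least 0.2 RPKM, and 0.657, 0.645 and 0.671 thinned, with 0.784 to 0.822 for 1000 cells on leaving out single libraries. H3K27me3 correlations at 10000 and 1000 cells were 0.836 and 0.734 as Pearson, 0.862 and 0.749 with a pseudocount of 1, 0.796 and 0.711 with 0.01, 0.845 and 0.748 over all bins, 0.723 and 0.556 from 0.2 RPKM, and 0.777 and 0.680 thinned. H3K4me3 correlations at 10000 and 5000 cells were 0.869 and 0.848 as Pearson, 0.929 and 0.924 with a pseudocount of 1, 0.801 and 0.751 with 0.01, 0.886 and 0.865 from 0.2 RPKM, 0.909 and 0.894 with 1 window per gene, and 0.777 and 0.757 thinned, with 0.863 at 5000 cells over all windows.

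Recovery with the top 1% was 62.4%, 62.6% and 66.7% for H3K9me3 at 100000, 10000 and 1000 cells, 77.1% and 58.9% for H3K27me3 at 10000 and 1000 cells, and 33.6% and 36.9% for H3K4me3 at 10000 and 5000 cells. Thinned, the same shares were 57.6%, 59.97%, 61.2%, 65.4%, 52.3%, 44.3% and 44.4%. With the top 10% they were 58.8% for H3K27me3 at 1000 cells and 70.1% and 69.9% for H3K4me3, and after subtraction of panH3 66.99% and 50.1% for H3K27me3. Leaving out single H3K9me3 libraries gave 72.1% to 75.2%. The share of top H3K27me3 genes with RNA under the threshold was 73.1% at 0.5 RPKM, 95.2% at 5 RPKM, and 78.3% at 1 RPKM among genes with RNA above 0, where 43.7%, 70.9% and 36.8% of all genes lay under it. Their correlation was -0.445 and -0.452 with H3K27me3 at 10000 and 100000 cells, -0.432 with RNA above 0 and -0.328 over all transcripts.

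The ratio of shared H3K9me3 and H3K27me3 bins to independent lists at 100000, 10000 and 1000 cells was 4.18, 2.42 and 4.60 for the top 1% and 1.23, 0.867 and 1.69 after division by panH3, the value at 10000 cells being the one that reversed. With the top 10% it was 2.21 at 100000 and 2.61 at 1000 cells, and 3.08 at 1000 cells without the bins highest in panH3. With the mean over the rows of a gene, list percentiles were 64.9 for pluripotency genes in H3K27me3 at 1000 cells, and in H3K4me3 at 100000 cells 99.9 for pluripotency genes, 33.8 for HOX genes and 88.8 for lineage regulators. That setting moved 59 of 99 list percentiles and a pseudocount of 1 moved 16, and none reversed from high to low.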

Other observations

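The tests of depth and of unenriched chromatin for H3K4me3 were laid down before their results were seen; all tests on chromosomes and the grouping of genes by H3K27me3, H3K4me3 and RNA were chosen only after the result was seen. H3K4me3, H3K27me3 and RNA could be set side by side for 20317 genes. Genes with RNA of at least 1 RPKM and H3K27me3 under 1 RPKM at 100000 cells (10121 genes) had median H3K4me3 of 4.64, 24.4 and 11.3 RPKM at 100000, 10000 and 5000 cells, and genes low in both (8224) had 0.48, 0 and 0.54. Genes with H3K27me3 of at least 1 RPKM and RNA under 1 RPKM (1586) lay between, at 1.32, 2.81 and 1.62, and 36.3% of them reached 4 RPKM of H3K4me3 at 10000 cells, against 19.1% of the genes low in both and 89.3% of the expressed genes without H3K27me3. The 386 genes with H3K27me3 and RNA both at 1 RPKM or more had 3.16, 11.3 and 5.39 RPKM, and 78.2% reached 4. Each mark was taken from the row of a gene with its highest mean, so the marks can come from different start sites. For Esrrb the H3K27me3 row started at 87762592 on chromosome 12 and the H3K4me3 window at 87810567. These groups therefore do not show marks on the same promoter. Across genes, H3K4me3 correlated with RNA at a Spearman coefficient of 0.757, 0.770 and 0.760 at 100000, 10000 and 5000 cells.

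Chromosomes 1, 8 and 11 stood at 1.30 to 1.64 times the other autosomes in all bin libraries, and the end of chromosome 6 at 1.49 to 1.72 in panH3, where alone it was measured. Gene density is argued against, since in bins that touch no gene the lowest of the 3 chromosomes still stood at 1.48 in panH3. The choice of bins was not decided. At most 7.46% of the positions on these chromosomes were deposited, inside the range of 7.13% to 7.57% on the 15 others. An equal share of positions does not show that the bins kept were alike in level. A candidate explanation is extra copies of these chromosomes in this culture, for which every 10 Mb segment should be high, and the lowest segment on the 3 chromosomes was 1.34, above the highest of 1.18 elsewhere. Expressed genes there had a median RNA of 8.4 RPKM against 6.27, as high as in only 0.613% of 816 sets of 3 autosomes, but chromosomes 18 and 13, with bin levels near 1, had medians of 8.52 and 8.02 RPKM, so the RNA adds little. The explanation is left open, since the labels give no karyotype. In start-site windows of low rank the chromosomes stood at 1.26, 1.47 and 1.59, with X at 0.492, in H3K4me3 at 100000 cells. At 5000 cells they stood at 1.36, 1.28 and 1.43, but at 10000 cells at only 1.06, 1.02 and 1.12, with X at 0.848. These windows were ranked in the same H3K4me3 libraries, which limits their levels. The 10000-cell library is also shallow, so its values cannot decide the question.

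H3K4me3 contrast was 17.4 at 100000 cells, 126 at 10000 and 59.98 at 5000, so that the library with the most cells had the least. Depth was not decided by thinning to equal library totals, after which the contrast at 5000 cells was 2.67 times that at 100000 cells. Thinning a library's own reads can hardly move a ratio of means, as at 100000 cells (17.4 to 17.3). The contrast fell from 126 to 80.1 at 10000 cells and from 59.98 to 46.1 at 5000 cells. The 10000-cell library is the shallowest and kept its reads, so its fall came from ranking windows in the thinned other libraries. Unenriched chromatin among the reads at 100000 cells also remains open and may account for it, since the signal above background fell short of that at 10000 cells by similar factors in windows of high and middle signal (ratios of 0.137 and 0.183, or 0.746 of each other), a test limited by the absence of windows above 50 RPKM. No biological explanation was tested.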
